A study of Arabidopsis thaliana with 12 samples.

How the data were processed

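RNA was taken from whole rosettes of Arabidopsis plants of 4 genotypes, with 3 libraries per genotype and about 20 plants pooled per library. Plants grew for 18 days on peat and 7 days on soil under 16 h of light at 20 °C. The deposited table of RSEM expected counts was made by the authors with RSEM 1.2.25 at default parameters, per the file headers, and holds 33323 genes of chromosomes 1 to 5, with 3.423% of the values not whole and no scaling between libraries. The deposited table of TPM values was made by the authors in the same RSEM run, per the file headers, and each of its columns sums to 1000000. The notes name the genome as TAIR10. The aligner, trimming, strand setting and annotation release are not stated. Reads were not realigned. Gene coordinates and symbols come from RefSeq TAIR10.1, where 32835 of the gene identifiers were found and 488 were not, and no organelle genes are in the table.

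Expected counts were rounded and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr (19059 genes left), one quasi-likelihood model of all 12 libraries with a term per genotype, and Benjamini-Hochberg adjustment over all genes within a comparison, with genes called at an adjusted p below 0.05. The comparisons were cdk8-1 with Col-0, jazD with Col-0, jazDcdk8-1 with jazD, jazDcdk8-1 with Col-0, and the difference of the cdk8-1 effect between the 2 JAZ backgrounds (interaction). Errors on log2 fold changes are the absolute log2 fold change divided by the square root of its F statistic. They are approximate standard errors and are too small where a group holds few counts. CPM are means ± SD over 3 libraries, and both are on TMM-scaled counts. The common dispersion was 0.002566, low for pools of plants. Total counts ran from 17583467 to 21030374 per library, and a gene with 3 counts or fewer over a group is given by its counts.

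The comparisons, 40 gene lists with 503 members, the rule for named genes and most alternatives were set before the data were examined. Lists were tested with camera (limma 3.58.1, preset correlation of 0.01) over the 40 lists, and again with an estimated correlation and with fry. List counts are also given with p-values adjusted over the list alone. Named genes follow a rule. It takes CDK8 with its module partners, the JAZ genes, AOX1A, PDF1.2A, ASA1, CYP79B2, VSP2, LOX2 and PR1 whatever their call, and per list and comparison up to 4 called members with the largest change and at least 1 CPM. It adds per comparison the 6 highest and 6 lowest called genes with at least 5 CPM and no overlap between replicates of the 2 groups. For the interaction it adds 5 of each sign. There the replicates had to be free of overlap between jazD and jazDcdk8-1 or between Col-0 and cdk8-1. The rule picked 313 genes. A gene it picked in one comparison is sometimes followed into another, such as ORA59, PR4 and DTX18. These uses, BHLH100, the genes of the chromosome 5 interval and those shown per library in cdk8-1 replicate 3 were chosen after their values were seen.

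On simulated data with the dispersion of these libraries, the same model recovered 77.6% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes in jazDcdk8-1 against jazD (59.7%, 88.1% and 100% for the interaction). The changed genes were drawn among those with a mean above 2 CPM, so these rates do not cover genes of lower counts. The model called 4 to 21 unchanged genes per comparison, with 18885 genes tested, changed ones included. A list spiked in the simulation gave adjusted p = 1.11e-57, and 0 of 39 random lists were called by camera. The simulated genes were drawn independently, so this does not test the preset correlation on lists whose members are correlated. Overlaps of comparisons that share libraries were also counted in 20 simulations, in which jazDcdk8-1 was drawn at the level of jazD or of Col-0. Alternatives were RLE scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), models of 2 groups only, a minimum change of 2-fold, removal of the 20 most abundant genes, a block for replicate number, and each library left out in turn. Total-count scaling and removal of the chromosome 5 interval from the finished results, without a new fit or adjustment, were added after the data were seen. Among genes at least 4-fold lower in jazD, the positions of those back in jazDcdk8-1 were set against 1000 draws of as many returns, made separately inside and outside 17 to 24 Mb of chromosome 5 and for deeper and smaller falls, with copies of the same fold changes taken once. All 10 splits of the 6 libraries were run for each comparison of 2 groups, and 40 of the 200 for the interaction.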

Results

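Whole rosettes of Arabidopsis thaliana were compared in 4 genotypes: the wild type Col-0, the CDK8 mutant cdk8-1, the jasmonate-hyperactive mutant jazD, and their combination jazDcdk8-1. CDK8 is a kinase of the Mediator complex, which links transcription factors to RNA polymerase II. JAZ proteins repress the transcription factors that switch on jasmonate defense, and jazD combines mutations in 10 of the 13 JAZ genes. Each genotype has 3 libraries, each from an independent pool of about 20 plants, so p-values of single genes test differences against the spread between pools of plants. P-values of gene lists (camera) set a list against the other genes, at a preset correlation of 0.01. Estimated correlations were often higher, such as 0.316 for ERF-branch defense in jazD against Col-0. Very small list p-values thus overstate the evidence, and values with an estimated correlation are printed mainly where a call was lost. Total counts ran from 17583467 to 21030374 per library, and 19059 genes had enough counts to be tested.

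The 4 genotypes formed 4 separate groups. Correlations of log2 CPM (counts scaled to library size) ran from 0.99 to 0.9925 between libraries of one genotype and from 0.9289 to 0.9811 between genotypes. The first principal component (54.4% of the variance) placed jazD apart from the rest, with jazDcdk8-1 between jazD and the 2 genotypes with intact JAZ genes. The second component (18.9%) ordered the genotypes from Col-0 through jazD and cdk8-1 to jazDcdk8-1.

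**Figure D1:**
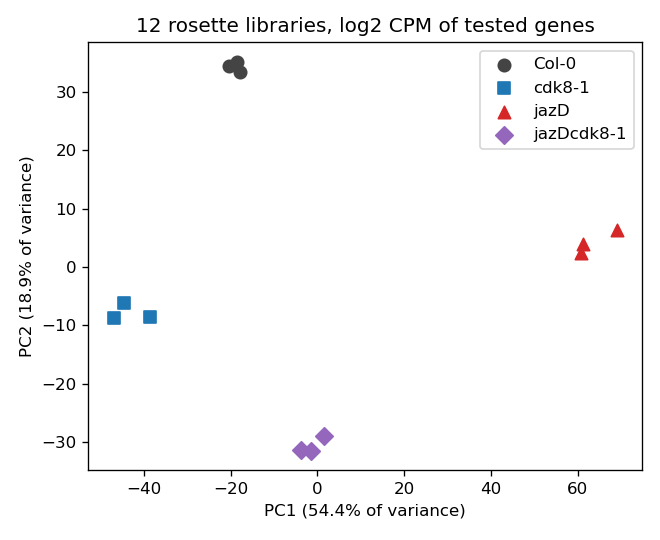
First 2 principal components of log2 CPM for the 12 libraries, with the share of variance on each axis and one symbol per library. The 3 libraries of each genotype lie together, and jazDcdk8-1 lies near 0 on the first component, where jazD lies between 60.8 and 69.0.

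The mutated genes were checked first. CDK8 (chromosome 5, 25463362 to 25465922, RefSeq TAIR10.1 coordinates) had 335, 370 and 406 counts in the Col-0 libraries and 46, 53 and 55 in cdk8-1. It had 388, 409 and 339 counts in jazD and 49, 69 and 71 in jazDcdk8-1. As CPM of CDK8 (mean ± SD, n = 3) this is 18.8 ± 1.46, 2.56 ± 0.234, 20.4 ± 0.602 and 3.11 ± 0.329. CDK8 thus fell 7.32-fold in cdk8-1 against Col-0 (adjusted p = 7.98e-14) and 6.53-fold in jazDcdk8-1 against jazD (adjusted p = 6.24e-15). Its kinase module partners stayed close to their Col-0 level. CYCC1;1, a C-type cyclin, rose by 0.35 ± 0.10 log2 in cdk8-1 (adjusted p = 0.0112, not called without Col-0 replicate 2), while MED12 (0.00 ± 0.06, adjusted p = 0.973) and MED13 (-0.07 ± 0.07, adjusted p = 0.564) were not called there.

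Of the JAZ genes mutated in jazD, 5 fell in jazD, 4 of them more than 2-fold. JAZ1 went from 11.5 ± 0.711 CPM in Col-0 to 2.38 ± 0.149 in jazD, JAZ2 from 24.3 ± 2.96 to 2.94 ± 0.474 and JAZ6 from 33.3 ± 3.83 to 2.99 ± 0.286. JAZ4 went from 0.707 ± 0.171 to 0.245 ± 0.115 CPM and lost its call without Col-0 replicate 2 or jazD replicate 3. JAZ3 and JAZ9 differed less: JAZ3 fell by 0.20 ± 0.06 log2 and JAZ9 rose by 0.17 ± 0.05. The JAZ3 call was lost without Col-0 replicate 1 or jazD replicate 2. The JAZ9 call was lost without Col-0 replicate 3, and also with limma on log2(TPM + 1) (0.1, adjusted p = 0.2027). JAZ5 was not called (-0.29 ± 0.23, adjusted p = 0.332). JAZ10 and JAZ13 carried more counts in jazD than in Col-0 (9.35 ± 2.15 against 2.08 ± 0.418 CPM, and 1.46 ± 0.123 against 0.0853 ± 0.061). A count does not tell whether these transcripts are intact. JAZ7 had 6 counts over the 3 Col-0 libraries, 11 in cdk8-1, 1 in jazD and 1 in jazDcdk8-1, too few to test. Of the 3 JAZ genes left intact, JAZ8 rose 19.6-fold in jazD (0.153 ± 0.136 to 3.09 ± 0.463 CPM), JAZ12 rose 1.25-fold and JAZ11 was not called (0.04 ± 0.10).

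In jazD against Col-0 the jasmonate pathway and its defense outputs rose together. All 11 tested ERF-branch defense genes rose, with a median of 5.56 log2 (camera adjusted p = 1.86e-15), as did 13 of 16 MYC-branch genes (median 2.88, adjusted p = 1.17e-75). All 9 tested genes of ER bodies, the compartments that store defensive beta-glucosidases, rose by a median of 3.41 (adjusted p = 2.00e-89). With an estimated correlation the camera adjusted p was 0.0133 for the ERF branch, 0.000168 for the MYC branch and 2.28e-05 for ER bodies. The defensin gene PDF1.2A went from 3.84 ± 2.03 to 2179 ± 76.6 CPM and VSP2, a vegetative storage protein gene induced by wounding, from 17.7 ± 1.09 to 1169 ± 28.3. The jasmonate synthesis gene LOX2 went from 564.7 ± 8.18 to 4825 ± 119 CPM.

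Jasmonate metabolism rose on both sides. Of 13 tested synthesis genes 12 rose and JAR1, which conjugates jasmonate to isoleucine, fell by 0.17 ± 0.06 log2, a call lost without Col-0 replicate 3 or either of jazD replicates 2 and 3. AOC1 rose by 3.24 ± 0.06, LOX2 by 3.09 ± 0.05 and AOC2 by 2.78 ± 0.05 (median of the list 1.41, adjusted p = 6.45e-54). All 8 tested genes of jasmonate breakdown rose, among them the jasmonate oxidase genes JOX2 (4.22 ± 0.07), JOX3 (3.42 ± 0.15) and JOX4 (3.22 ± 0.27). Of 10 transcription factor and receptor genes 6 rose, led by MYC2 (1.71 ± 0.07) and JAM1 (1.00 ± 0.07), and 2 fell, MYC4 (-0.26 ± 0.07) and MYC5 (-2.06 ± 0.68), which is below 1 CPM in each genotype and lies in the chromosome 5 interval described below. The test for that list gave an adjusted p of 0.00525, and adjusted p = 0.204 with an estimated correlation. The counts for these groups were the same when adjusted over each list alone.

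Defensin genes and ACT were among the defense genes with the highest folds. ACT, which makes coumaroylagmatine, an antifungal amide, went from 0.537 ± 0.381 to 422 ± 25 CPM, and its exporter gene DTX18 from 3.83 ± 1.02 to 244 ± 10.8. ADC1 and ADC2, which supply agmatine, rose by 0.72 ± 0.05 and 0.45 ± 0.04 log2, so all 4 genes of this list rose (adjusted p = 7.21e-17). PDF1.3, PDF1.2C and PDF1.2B rose by 10.86 ± 0.49, 10.28 ± 0.32 and 9.41 ± 0.27. These defensin genes are near-identical copies, so the division of reads between them is uncertain. ORA59, the ERF factor of this branch, rose 47.0-fold. VSP1 rose by 6.54 ± 0.18, the acetyltransferase gene NATA1 by 6.05 ± 0.17 and the terpene synthase gene TPS10 by 5.70 ± 0.24. In the ER body list BGLU18 rose by 4.1 ± 0.06, PBP1 by 3.79 ± 0.06 and TSA1 by 3.74 ± 0.06.

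Genes of tryptophan, serine and indole glucosinolate synthesis rose in part. Of 12 tryptophan synthesis genes 8 rose and 1 fell (8 and 2 when adjusted over the list alone), with a median of 1.12 log2 (adjusted p = 1.18e-11). ASA1, the entry enzyme, went from 37.5 ± 4.49 to 83.4 ± 7.42 CPM, and TSB1 rose by 1.74 ± 0.05. The falling member, ASB2 (-2.30 ± 0.11), lies in the chromosome 5 interval described below, as does TSB1. In the phosphorylated serine pathway 3 of 5 genes rose and 1 fell, led by PGDH2 (1.68 ± 0.09) and PSAT1 (1.21 ± 0.05). The camera test of that list gave adjusted p = 0.000428, and adjusted p = 0.0405 with an estimated correlation. Of 19 indole glucosinolate genes 16 rose and 3 fell (median 1.08, adjusted p = 1.82e-33), with IGMT5 at 4.36 ± 0.11 and CYP81F4 at 3.66 ± 0.09, both modifying the indole ring, and CYP81F3 at -1.11 ± 0.13.

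Methionine-derived glucosinolate genes went the other way. Of 24 aliphatic glucosinolate genes 20 fell (median -0.42), MAM3 by 0.84 ± 0.11 and AOP2 by 0.77 ± 0.07 log2. Their camera test gave adjusted p = 5.24e-08, and adjusted p = 0.204 with an estimated correlation. Of 22 flavonoid and anthocyanin genes 17 rose and 1 fell (17 and 2 over the list alone; median 1.04, adjusted p = 6.46e-15). LDOX (2.87 ± 0.09) and DFR (2.58 ± 0.10) act late in anthocyanin synthesis, and the flavonol gene FLS1 was not called (-0.02 ± 0.07). All 5 camalexin genes rose, PAD3 by 2.53 ± 0.30 (adjusted p = 0.000389 for the list, and adjusted p = 0.2135 with an estimated correlation). Of 17 salicylic acid genes 7 rose and 2 fell, which did not pass the list test (adjusted p = 0.330), and PR1 rose by 1.71 ± 0.34 (not called by DESeq2, adjusted p = 0.0521).

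Photosynthesis genes fell in part in jazD, and so did photorespiration genes. Of 36 photosynthesis genes 20 fell (median -0.15, adjusted p = 6.66e-05, and adjusted p = 0.5625 with an estimated correlation). The carbonic anhydrase gene CA1 went from 3604 ± 107 to 2084 ± 113 CPM and RCA, which activates Rubisco, from 8680 ± 189 to 5320 ± 222. All 11 photorespiration genes fell (median -0.30, adjusted p = 6.15e-08, and adjusted p = 0.1525 with an estimated correlation), the catalase gene CAT2 by 0.89 ± 0.05 and the glycine decarboxylase gene GLDP1 by 0.68 ± 0.04. Of 17 sugar starvation genes 10 rose and 1 fell, with BCAT2, an enzyme of branched-chain amino acid breakdown, at 4.09 ± 0.20. That list gave adjusted p = 0.00393, and adjusted p = 0.2135 with an estimated correlation.

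Over all genes, jazD against Col-0 gave 4162 genes higher and 3991 lower at an adjusted p below 0.05 (edgeR quasi-likelihood F-test, TMM scaling, n = 3 against 3), of which 817 and 435 changed at least 2-fold. The 6 highest by the set rule were AT5G28810, PDF1.3, PDF1.2C, AT5G47260, ACT and PDF1.2B. AT5G28810 had 0 counts in Col-0 and 1682 in jazD, at least 597-fold higher, and AT5G47260 had 0 and 297, at least 105-fold higher (floor of 3 counts over the group). The 6 lowest were AT5G50565 (496 counts in Col-0 and 0 in jazD, at least 155-fold lower), AT5G49440 (-9.49 log2, 6 counts over the jazD group), AT5G45490 (-9.42 log2, 5 counts over the jazD group), AT5G49640, AT5G51630 and AT5G50665. All 6 lie on chromosome 5 between 17 and 24 Mb, and of the 84 genes at least 4-fold lower in jazD 42 lie in that interval, which holds 6.71% of the tested genes. The interval also holds, among other genes, MYC5, DFR, PDF1.2A, PDF1.2C, CYCC1;1, UGT79B1, CYP81F2 and MYB111. The share of called genes that were higher was 51.0%, and 44.5% with total counts in place of TMM. It was 38.1% with limma on log2(TPM + 1), which changes test, pseudocount and scaling together. Touch and early-stress genes, a list kept as a check on sampling, also rose, 7 of 8 (median 1.17, camera adjusted p = 0.0173, and adjusted p = 0.406 with an estimated correlation). Whether differences in sampling moved these genes, or stress-induced defense genes with them, was not tested. Among clock genes CCA1 fell by 1.58 ± 0.07 and LHY by 1.29 ± 0.12 while ELF4 rose by 2.07 ± 0.16.

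**Figure D2:**
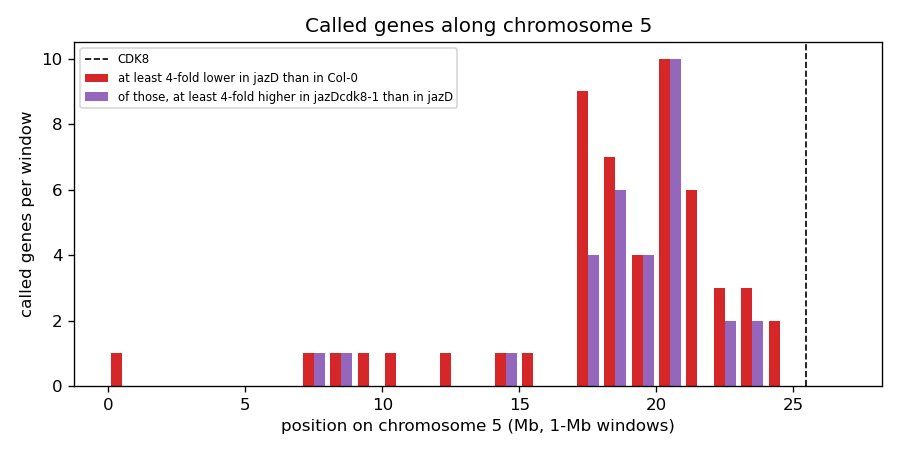
Number of called genes in 1-Mb windows along chromosome 5 that are at least 4-fold lower in jazD than in Col-0 (red), and how many of those are at least 4-fold higher in jazDcdk8-1 than in jazD (purple); the dashed line marks CDK8. The window from 20 to 21 Mb holds 10 of each kind, and the window from 21 to 22 Mb holds 6 and 0.

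In jazDcdk8-1 against jazD the defense genes that were high in jazD fell. All 11 ERF-branch genes fell (median -3.41, adjusted p = 1.68e-16), PDF1.2A from 2179 ± 76.6 to 51.5 ± 10.4 CPM and PR4, a chitin-binding defense protein gene, from 1746 ± 81.8 to 165 ± 7.48. ACT fell 68.3-fold to 6.28 ± 2.16 CPM and DTX18 28.8-fold to 8.43 ± 0.678. Of 16 MYC-branch genes 13 fell and 1, the myrosinase gene TGG1, rose by 0.79 ± 0.05 (13 became 14 over the list alone; median -2.03, adjusted p = 4.65e-40). ER body genes fell less: all 9 were lower, by a median of -0.59 (adjusted p = 3.68e-11), and BGLU18 was at 4982 ± 279 CPM.

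Jasmonate synthesis and breakdown genes fell in the same comparison. Of 13 synthesis genes 11 fell and JAR1 rose by 0.26 ± 0.06 (median -0.48, adjusted p = 1.92e-10), LOX4 by 1.97 ± 0.09 and LOX2 1.67-fold. All 8 breakdown genes fell (median -1.03, adjusted p = 5.32e-13), JOX3 by 3.61 ± 0.15 and JOX4 by 3.54 ± 0.28. Of 12 JAZ genes 7 fell, JAZ13 by 3.40 ± 0.45, JAZ8 by 2.62 ± 0.32 and JAZ10 by 1.63 ± 0.16 (when adjusted over the list alone 7 fell and 1 rose). The list gave adjusted p = 0.0029, and adjusted p = 0.1215 with an estimated correlation. Of 10 transcription factor and receptor genes 3 rose and 2 fell (4 and 2 over the list alone), with a camera adjusted p of 0.2926. MYC2 fell by 0.30 ± 0.06 (not called with limma on log2(TPM + 1)), and MYC4 rose by 0.47 ± 0.07 and MYC5 by 3.05 ± 0.58.

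Within defense metabolism, indole glucosinolate genes fell (15 of 19, 1 rose; median -0.74, adjusted p = 2.13e-32), with CYP81F4 at -3.27 ± 0.09, CYP81F2 at -3.19 ± 0.19 and IGMT5 at -2.61 ± 0.09. CYP79B2, which starts the pathway, was not called (-0.12 ± 0.06, adjusted p = 0.148). CYP81F2 lies in the chromosome 5 interval described above. Of 12 tryptophan genes 8 fell and 1 rose (median -0.69, camera adjusted p = 2.48e-07, and adjusted p = 0.0374 with an estimated correlation). ASA1 fell 2.15-fold to 38.9 ± 1.17 CPM and TSB1 by 1.25 ± 0.05. In contrast ASB2 rose by 2.26 ± 0.12 to 11.5 ± 0.497 CPM, near its Col-0 level of 11.8 ± 0.484. PGDH2, PGDH1 and PSAT1 of the serine pathway fell by 1.36 ± 0.08, 0.59 ± 0.05 and 0.58 ± 0.05. The camera test of that list gave adjusted p = 0.000303, and adjusted p = 0.0437 with an estimated correlation. DHS1, the first enzyme of the shikimate pathway, fell by 1.04 ± 0.04, among 6 of 15 genes that fell and 1 that rose (adjusted p = 0.00558, and adjusted p = 0.0931 with an estimated correlation). With limma on log2(TPM + 1) 4 of the 15 fell and 5 rose.

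Aliphatic glucosinolate genes rose, 14 of 24, with 2 that fell (16 and 3 over the list alone; median 0.31). MAM3 rose by 1.67 ± 0.10, IPMI2 by 0.98 ± 0.05 and SOT18 by 0.79 ± 0.05, while GSTF11 fell by 0.46 ± 0.11. The list gave adjusted p = 1.12e-09, and adjusted p = 0.122 with an estimated correlation. Flavonoid genes were split: 10 of 22 fell and 3 rose (median -0.17, adjusted p = 0.167), with TT8 at -1.11 ± 0.20, UGT75C1 at -1.14 ± 0.07, FLS1 at 1.00 ± 0.07 and MYB111 at 1.56 ± 0.19. Salicylic acid genes fell, 11 of 17, led by FMO1 (-4.37 ± 0.57), PR1 (-3.94 ± 0.43) and ALD1 (-3.60 ± 0.41). Their list gave adjusted p = 0.000127, and adjusted p = 0.369 with an estimated correlation. All 5 camalexin genes fell, with PAD3 at -3.82 ± 0.34 (adjusted p = 1.39e-05, and adjusted p = 0.133 with an estimated correlation).

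Photorespiration genes rose in part (6 of 11, 2 fell; median 0.13, adjusted p = 0.0159, and adjusted p = 0.403 with an estimated correlation), with GLDP1 at 0.48 ± 0.04 and CAT2 at 0.40 ± 0.05. Photosynthesis genes took no common direction: 7 rose and 13 fell (7 and 14 over the list alone) with a median of -0.10 under TMM. With total counts 14 rose and 12 fell (median -0.03), and with limma on log2(TPM + 1) 16 and 6 (median 0.06). RCA rose by 0.35 ± 0.05 and CA1 by 0.28 ± 0.05, still below Col-0. Of 17 sugar starvation genes 11 fell and 2 rose, BCAT2 by -3.99 ± 0.20 and SEN1 by -1.83 ± 0.12 (adjusted p = 0.000127, and adjusted p = 0.1215 with an estimated correlation). Senescence genes NAP (-2.21 ± 0.27), SAG13 (-2.05 ± 0.33) and ORE1 (-1.56 ± 0.33) fell, among 6 of 13 that fell and 3 that rose (adjusted p = 0.161).

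The comparison of jazDcdk8-1 with jazD gave 3213 genes higher and 3612 lower, of which 298 and 850 changed at least 2-fold. The 6 highest were the 6 chromosome 5 genes lowest in jazD, AT5G50565 with 0 counts in jazD and 484 in jazDcdk8-1 (at least 148-fold higher) and AT5G49440 at 97.0 ± 7.99 CPM against 0.118 ± 0.205. The 6 lowest were AT5G47260, AT2G43580, DIN11 (-7.12 ± 0.19), PDF1.3 (-7.03 ± 0.36), PDF1.2C (-6.83 ± 0.24) and PDF1.2B (-6.81 ± 0.21). AT2G43580 had 414 counts in jazD and 2 in jazDcdk8-1, a ratio of 225 (95% counting interval 61.9 to 1870). AT5G47260 had 297 and 1, a ratio of 323 (57.5 to 12800). The share of called genes that were higher was 47.1%. With total counts in place of TMM it was 63.5%, with 357 genes at least 2-fold higher and 771 lower. With limma on log2(TPM + 1), which changes test, pseudocount and scaling together, it was 76.1%, with 163 and 412 and a median of all genes of 0.132 log2. Touch and early-stress genes, the sampling check, fell as the defense genes did, 7 of 8, WRKY40 by 2.72 ± 0.30 and ZAT10 by 2.26 ± 0.18 (median -1.72, camera adjusted p = 2.24e-05, and adjusted p = 0.133 with an estimated correlation).

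**Figure D3:**
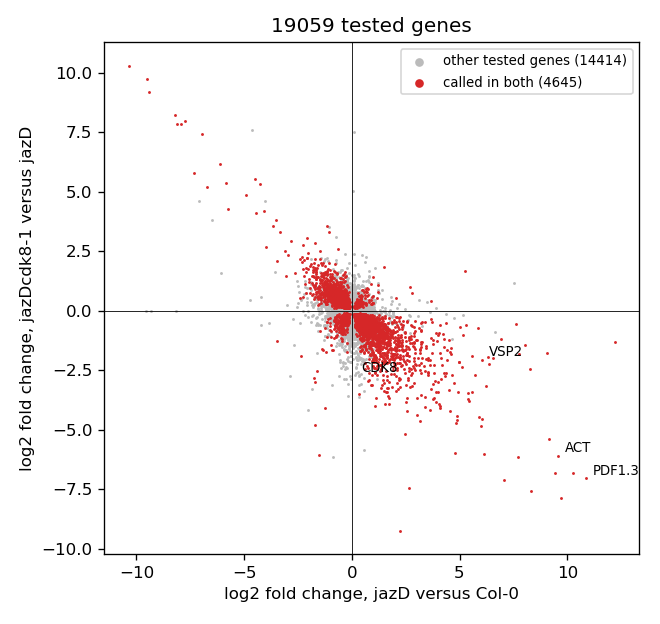
Log2 fold change of jazDcdk8-1 against jazD (vertical) over that of jazD against Col-0 (horizontal) for the 19059 tested genes, with the genes called in both comparisons in red. Most red points lie at the upper left and lower right, and the jazD libraries enter both axes with opposite sign.

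Of the 4162 genes higher in jazD than in Col-0, 2308 (55.5%) were lower in jazDcdk8-1 than in jazD, and of the 3991 lower genes 1960 (49.1%) were higher again. With total counts in place of TMM these overlaps were 1776 and 2644, and with limma on log2(TPM + 1) 1315 and 3334, so which of them is larger depends on these choices. Independent lists of these sizes would share 788.8 and 672.8. With jazDcdk8-1 simulated at the jazD level, the overlaps averaged 0.8 and 0.1 genes over 20 simulations. Only 1.5 genes on average were called in jazDcdk8-1 against jazD there. These overlaps could thus only be small and give no reference for the real ones. Part of the excess over independent lists may come from the jazD libraries that both comparisons share. A group of 3 libraries cannot be split so that both parts hold 2. Among the 817 genes at least 2-fold higher in jazD, VSP2 and LOX2 among them, 714 moved back, 416 were still called higher than in Col-0, and 335 moved back and were not called against Col-0. The median of these 817 went from 1.66 to 0.57 log2. Among the 435 at least 2-fold lower, 241 moved back and 253 were still called lower, with medians of -1.40 and -0.71.

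In plants with all JAZ genes, defense genes fell in cdk8-1 from an already low level and flavonoid genes rose. Of 16 MYC-branch genes 11 fell and TGG1 rose (12 and 1 over the list alone; median -1.14, adjusted p = 1.39e-18). The terpene synthase genes TPS04 and TPS03 fell by 3.08 ± 0.31 and 2.66 ± 0.25, TAT3 by 2.39 ± 0.27, and VSP2 went from 17.7 ± 1.09 to 6.91 ± 3.04 CPM. Of 22 flavonoid genes 14 rose and 2 fell (14 and 3 over the list alone; median 0.65, adjusted p = 2.16e-12), with FLS1 at 1.52 ± 0.06, MYB111 at 1.36 ± 0.16 and CHIL at 1.16 ± 0.08. Both lists kept their call with an estimated correlation (adjusted p = 0.0185 for each).

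Other defense lists fell in part in cdk8-1. Of 17 salicylic acid genes 10 fell (12 over the list alone), ALD1 by 2.97 ± 0.41 and PR1 from 20.5 ± 10.6 to 4.91 ± 2.01 CPM (adjusted p = 0.00235, and adjusted p = 0.471 with an estimated correlation). Of 19 indole glucosinolate genes 9 fell and 4 rose (10 and 5 over the list alone), CYP81F2 by -2.30 ± 0.31, IGMT2 by -1.81 ± 0.40 and CYP79B2 by 0.26 ± 0.07 (adjusted p = 0.00367, and adjusted p = 0.182 with an estimated correlation). Of 5 camalexin genes 4 fell, PAD3 by 2.69 ± 0.54 (adjusted p = 0.00701, and adjusted p = 0.373 with an estimated correlation). Of 8 jasmonate breakdown genes 6 fell (7 over the list alone), JOX3 by 1.38 ± 0.25 and ILL6 by 0.99 ± 0.10 (adjusted p = 0.00241, and adjusted p = 0.159 with an estimated correlation). Jasmonate synthesis genes gave 6 lower and 2 higher of 13 (6 and 3 over the list alone) with a median of -0.05 (0.02 with total counts and 0.03 with limma on log2(TPM + 1)), and LOX4 fell by 1.37 ± 0.13.

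In the ERF branch 5 of 11 genes fell in cdk8-1, ERF5 by 1.86 ± 0.35, PR4 by 1.67 ± 0.17 and PR3 by 1.32 ± 0.20, with a median of -0.04 (0.04 with total counts and -0.93 with limma on log2(TPM + 1)). The list gave adjusted p = 0.00429, and adjusted p = 0.373 with an estimated correlation. PDF1.2A (3.62 ± 5.69 CPM, -0.04 ± 0.64 log2), PDF1.2C (1.46 ± 2.27 CPM) and ACT (0.705 ± 1.22 CPM) were not called. Their counts in cdk8-1 came nearly all from replicate 3: PDF1.2A had 212 there and a mean of 6.5 in the other 2 libraries, PDF1.2C 85 and 3.0, and ACT 44 and 0.0. The same library also held more VSP2 (217 against 101.5), VSP1 (276 against 112.5) and PR4 (363 against 166.5). The agmatine list, which holds ACT, had a median of 0.24 and a mean of -0.38, and DTX18 fell by 2.74 ± 0.34. DTX18 had 26 counts in replicate 3 and a mean of 4 in the other 2 libraries, so the size of its fall depends on replicate 3. AOX1A, a mitochondrial alternative oxidase gene known as a CDK8 target, was not called (0.12 ± 0.05, adjusted p = 0.0901).

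Among the other groups, PYK10 of the ER body list rose from 42.9 ± 5.48 to 113 ± 5.95 CPM, with PBP1 (0.58 ± 0.06) and NAI2 (0.50 ± 0.08), while BGLU18 fell by 0.24 ± 0.05, a call lost with limma on log2(TPM + 1) (3 of 9 rose, 1 fell, 2 over the list alone; adjusted p = 0.00551, and adjusted p = 0.212 with an estimated correlation). Aliphatic glucosinolate genes gave 7 higher and 12 lower of 24 (7 and 13 over the list alone; adjusted p = 0.241), CYP79F2 by -1.10 ± 0.14 and MAM3 by 0.92 ± 0.09. Sulfate genes APR3 (0.98 ± 0.07) and LSU2 (0.83 ± 0.15) rose, among 6 of 16 that rose and 2 that fell (adjusted p = 0.0404, and adjusted p = 0.373 with an estimated correlation; this list call is also lost without Col-0 replicate 1 or 3 or cdk8-1 replicate 1). Of 36 photosynthesis genes 22 fell and 3 rose (23 and 3 over the list alone), LHCB1.4 by -0.62 ± 0.06 (median -0.22, adjusted p = 1.04e-06, and adjusted p = 0.471 with an estimated correlation). Of 17 sugar starvation genes 8 fell and 1 rose, SEN1 by -1.71 ± 0.14 and ASN1 by -1.69 ± 0.12 (adjusted p = 3.7e-05, and adjusted p = 0.159 with an estimated correlation).

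The comparison of cdk8-1 with Col-0 gave 2229 genes higher and 2624 lower, of which 189 and 471 changed at least 2-fold. The 6 highest were AT3G55230 (2.60 ± 0.18), AT1G11070 (2.51 ± 0.10), AT1G62290 (2.11 ± 0.09), AT5G26280 (2.03 ± 0.16), AT5G62210 (2.01 ± 0.09) and JAL22 (1.84 ± 0.12). The 6 lowest were AT4G01390 (-5.71 ± 0.25, from 7.28 ± 0.333 to 0.132 ± 0.0747 CPM), the beta-amylase gene BAM5 (-3.97 ± 0.23), TPS04, CDK8, AT1G15125 (-2.64 ± 0.19) and AT5G35480 (-2.46 ± 0.17). The share of called genes that were higher was 45.9% under TMM and 66.8% with total counts, so the balance of small changes depends on the scaling. With limma on log2(TPM + 1) it was 69.9%. Touch and early-stress genes, the sampling check, fell here too, 5 of 8 with 1 rising, WRKY40 by 2.07 ± 0.36 (camera adjusted p = 0.00343, and adjusted p = 0.373 with an estimated correlation).

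The effect of cdk8-1 was partly shared between the 2 JAZ backgrounds. Across all 19059 genes its log2 fold changes correlated with a Pearson coefficient of 0.524 and a Spearman coefficient of 0.446 (0.272 and 0.339 without a filter on low counts), and no library entered both comparisons. Of 2944 genes called in both, 89.1% changed in the same direction. AT4G01390 (-3.49 ± 0.17 in the jazD background), BAM5 (-2.90 ± 0.12), AT3G55230 (3.55 ± 0.22) and AT1G11070 (3.32 ± 0.12) were called the same way in both. Shared genes numbered 1118 among those higher and 1505 among those lower, where independent lists would share 375.8 and 497.3.

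Compared with wild type, part of the genes high in jazD were also high in jazDcdk8-1. ER body genes were higher in 8 of 9 cases, all 8 also higher in jazD (median 2.53, adjusted p = 3.35e-106), with BGLU18 at 4982 ± 279 CPM against 437.7 ± 26.9 in Col-0. Of 13 jasmonate synthesis genes 10 were higher (11 over the list alone), all 10 also in jazD (median 0.65, adjusted p = 1.37e-49), led by AOC1 (2.76 ± 0.06) and LOX2 (2.36 ± 0.05). Of 22 flavonoid genes 18 were higher (median 0.92, adjusted p = 2.01e-20), and 16 of the 18 were also higher in jazD. The flavonoid changes were led by UGT79B1 (2.21 ± 0.15), DFR (2.16 ± 0.10) and PAP1 (2.00 ± 0.14). Of 16 MYC-branch genes 12 were higher, all 12 also in jazD, and 2 lower (median 1.21, adjusted p = 5.74e-38), with VSP1 at 4.54 ± 0.18, MBP1 at 4.36 ± 0.08 and TAT3 at -2.62 ± 0.28.

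Several defense lists lay closer to the Col-0 level in jazDcdk8-1 than in jazD. ERF-branch genes were higher in 6 of 11 cases (median 2.17), PDF1.2A by 3.75 ± 0.41 and ORA59 by 3.65 ± 0.15 (adjusted p = 0.00137, and adjusted p = 0.290 with an estimated correlation). ACT was 11.3-fold above Col-0 and DTX18 2.21-fold. Of 12 tryptophan genes 6 rose and 1 fell (7 and 2 over the list alone; median 0.27, adjusted p = 0.000254, and adjusted p = 0.137 with an estimated correlation), and ASA1 was not called (0.05 ± 0.08). Of 19 indole glucosinolate genes 12 were higher and 4 lower, with CYP79B3 at 1.08 ± 0.06 (median 0.34, camera adjusted p = 6.64e-05, and adjusted p = 0.0461 with an estimated correlation).

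Salicylic acid and photosynthesis genes lay below Col-0 in part. Of 17 salicylic acid genes 9 were lower and 1 higher (10 and 1 over the list alone; median -0.58, against 0.29 in jazD), PR1 by -2.23 ± 0.48 and ALD1 by -3.26 ± 0.43 (adjusted p = 0.0124, and adjusted p = 0.658 with an estimated correlation). Photosynthesis genes were lower in 28 of 36 cases (30 over the list alone), RBCS2B by 0.71 ± 0.07 (median -0.24, adjusted p = 2.08e-09, and adjusted p = 0.473 with an estimated correlation), and photorespiration genes in 10 of 11 (11 over the list alone; adjusted p = 5.07e-06, and adjusted p = 0.236 with an estimated correlation).

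This comparison gave 3111 genes higher and 3062 lower, of which 369 and 521 changed at least 2-fold. The share of called genes that were higher was 50.4%. With total counts in place of TMM it was 60.1%, with 394 genes at least 2-fold higher and 480 lower. With limma on log2(TPM + 1) it was 67.6%, with 220 and 181, and test, pseudocount and scaling change together there. The 6 highest were AT5G28810 (0 counts in Col-0, 727 in jazDcdk8-1, at least 237-fold higher), PAO2 (7.61 ± 1.75), CSLA01 (7.05 ± 0.32), AT3G28220 (5.12 ± 0.14), AT1G14120 (4.68 ± 0.27) and VSP1. PAO2, which overlaps another annotated gene, ranged from 0.111 to 31.6 CPM between the 3 jazDcdk8-1 libraries, so its reads may be assigned differently from library to library. The PAO2 call was lost with limma on log2(TPM + 1) (2.75, adjusted p = 0.05025) and on log2(TPM + 0.1) (4.52, adjusted p = 0.05634). The 6 lowest were JAZ6 (-4.74 ± 0.13), TRM24 (-3.61 ± 0.25), AT4G01390 (-3.16 ± 0.18), the galactinol synthase gene GOLS3 (-2.98 ± 0.16), MRU1 (-2.96 ± 0.14) and JAZ2 (-2.78 ± 0.11). Of the genes called against Col-0, 1866 were higher and 1754 lower in both jazD and jazDcdk8-1. Independent lists would share 679.4 and 641.2. Simulations with jazDcdk8-1 at the Col-0 level gave 0.1 and 0.2. They called only 0.6 genes on average in jazDcdk8-1 against Col-0, so these overlaps could only be small and give no reference. Part of the excess over independent lists may come from the shared Col-0 libraries.

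**Figure D4:**
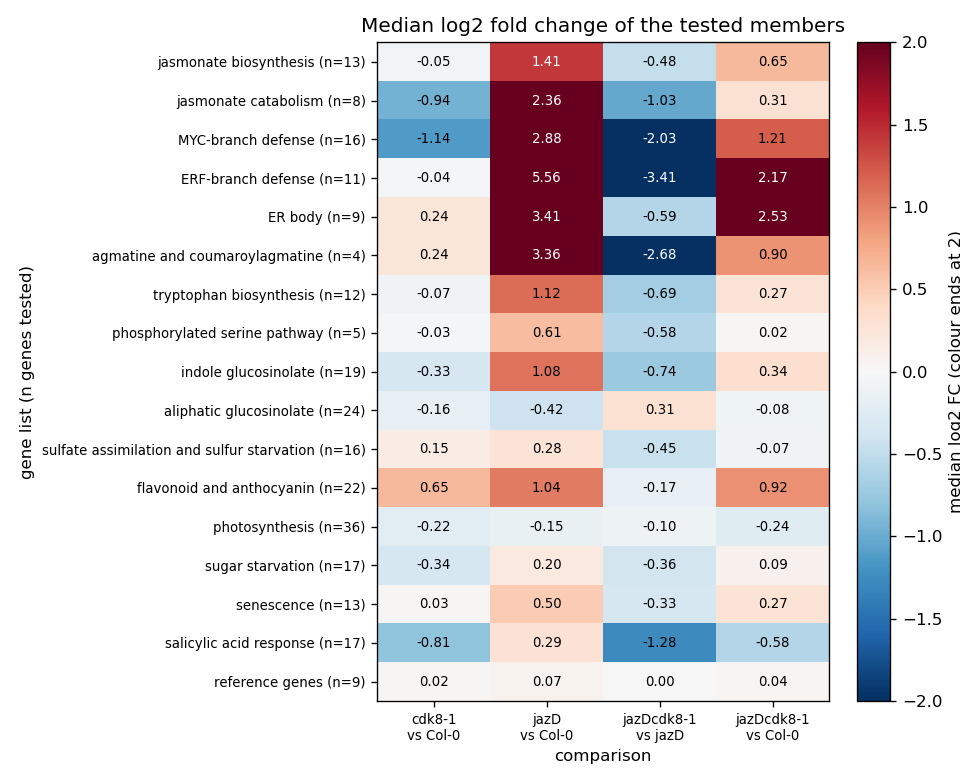
Median log2 fold change of the tested members of 17 gene lists (vertical, number of tested genes in brackets) in the 4 comparisons (horizontal), printed in each cell and coloured from blue (lower) to red (higher). ERF-branch defense has 5.56 in jazD against Col-0 and -3.41 in jazDcdk8-1 against jazD, and reference genes lie between 0.00 and 0.07 under TMM scaling (in jazDcdk8-1 against jazD 0.07 with total counts and 0.13 with limma on log2(TPM + 1)).

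The test of the difference between the backgrounds asked whether the change in cdk8-1 differed between jazD and Col-0, with a negative value where it was lower in the jazD background. ERF-branch genes fell further in the jazD background, 8 of 11 (9 over the list alone), with ORA59 at -1.88 ± 0.28, PR4 at -1.74 ± 0.22 and PDF1.2A at -5.37 ± 0.77 (adjusted p = 1.14e-07, and adjusted p = 0.0860 with an estimated correlation). All 4 agmatine genes were negative, ADC1 by -0.83 ± 0.07 and DTX18 by -2.10 ± 0.50 (adjusted p = 3.93e-08). For ACT the interaction was -6.52 ± 1.05. The values of PDF1.2A, DTX18 and ACT rest on cdk8-1 replicate 3. Without it PDF1.2A stands at -1.90 and DTX18 at -0.66, and ACT has no counts in cdk8-1, which leaves no size for it. None of the 3 is then called by edgeR. The negative genes then number 4 of 11 in the ERF branch (median -1.80) and 2 of 4 in the agmatine list, with adjusted p = 0.000254 for each list. Of 19 indole glucosinolate genes 12 were negative and 2 positive (13 and 2 over the list alone; median -0.53, adjusted p = 1.09e-18), with IGMT5 at -2.20 ± 0.20 and GSTF10 at -1.43 ± 0.06. ER body genes were negative in 7 of 9 cases (median -0.71, adjusted p = 4.6e-22), PBP1 by -1.99 ± 0.08 and PYK10 by -1.91 ± 0.10.

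Metabolic groups also differed between the backgrounds. Flavonoid genes were negative in 15 of 22 cases and positive in 1 (2 over the list alone; median -0.82, adjusted p = 1.13e-14), with LDOX at -1.57 ± 0.13. Sulfate genes were negative in 12 of 16 (median -0.48, adjusted p = 1.1e-11), APR3 by -1.97 ± 0.10 and LSU2 by -1.17 ± 0.24. Tryptophan genes were negative in 8 of 12 with 1 positive, ASB2, and TSB1 stood at -1.27 ± 0.07 (camera adjusted p = 1.15e-07 for the list, and adjusted p = 0.037 with an estimated correlation). Jasmonate synthesis genes were negative in 8 of 13 (10 over the list alone; adjusted p = 1.97e-07), AOC2 by -0.73 ± 0.07. Aliphatic glucosinolate genes were positive in 18 of 24 (21 over the list alone; median 0.40), with CYP79F2 at 1.2 ± 0.20, AOP2 at 1.18 ± 0.11 and CYP79F1 at 0.92 ± 0.07 (adjusted p = 1.93e-17, and adjusted p = 0.0514 with an estimated correlation). In all, 1555 genes had a positive interaction and 1599 a negative one. The share that was positive was 49.3%, 48.2% with total counts, and 60.3% with limma on log2(TPM + 1).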

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

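The tests of the chromosome 5 interval, of cdk8-1 replicate 3, of a jaz effect on the clock genes and of the splits of the libraries were chosen after the results they bear on were seen; the 2 tests of harvest hour used genes whose values had not been seen, after the clock list of the report had been.

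The effect of cdk8-1 differed between the 2 JAZ backgrounds, by a test of the difference itself, in 1555 genes with a positive and 1599 with a negative interaction. With the real grouping 3154 genes were called, and 1 of 40 drawn splits (of 200 possible) gave as many, the real one; the highest other gave 3050. The 5 other draws that kept the jazD and jazDcdk8-1 libraries whole gave the high counts, and the highest among the rest was 296. The count thus follows the contrast between these 2 groups. With a minimum change of 2-fold the real grouping gave 453 genes, and these 5 draws gave 374, 790, 910, 913 and 938. Col-0 and cdk8-1 libraries were mixed in these 5 draws, so the splits do not show that the cdk8-1 effect depends on the background. In the comparisons of 2 groups only 10 splits exist, too few for a share under 0.05; in each, 1 split, the real one, gave as many genes. The real counts and the highest others were 4853 and 1 for cdk8-1 against Col-0, 8153 and 0 for jazD against Col-0, 6825 and 1 for jazDcdk8-1 against jazD, and 6173 and 0 for jazDcdk8-1 against Col-0.

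The positive interactions named by the rule, with their fitted log2 values, were AT5G50565 (10.19), AT5G45490 (9.83), AT5G49440 (9.16), AT5G49640 (8.34) and AT5G51630 (7.95). All 5 lie between 17 and 24 Mb of chromosome 5. They are nearly silent in jazD (0 to 6 counts over the group; AT5G50565 has 0, so its 10.19 rests on a group without reads and only a fall of at least 155-fold below Col-0 can be given) and within 2-fold of the Col-0 level in cdk8-1 and jazDcdk8-1. Of 35 genes at least 4-fold lower in jazD and at least 4-fold higher again in jazDcdk8-1, 28 (80%) lie in this interval, 11.92 times its share of tested genes (bounds read off these same genes). A deletion of the whole interval is argued against by its median log2 fold change of -0.04 in jazD (quartiles -0.32 and 0.22). A return of low genes through loss of CDK8 wherever they lie was tested among the low genes themselves. Of 125 pairs of low genes in one 1-Mb window, 94 shared a fate, both back or both not. In 1000 draws of as many returns, made separately inside and outside the interval and for deeper and smaller falls, at most 92 did (median 69). AT5G50565 (start 20580113) and AT5G50665 (20613455) lie as far apart as AT5G50550 (20576733) and AT5G50650 (20610075), which were taken once as copies. The first pair differs in fold change and was counted as separate genes. The margin is small, so the draws cannot decide while possible copies are counted apart. The form of this test was also changed several times after earlier forms had been seen, and control shared by neighbouring genes was not tested. Segments of another strain carried by jazD and replaced in part in jazDcdk8-1 stay open as well. They may give such blocks, but the ratio of 11.92 was measured on the genes that drew attention to it. No sequence variants are in these tables. A single block replaced up to CDK8 is not what the windows show. From 20 to 21 Mb 10 of 10 low genes came back, copies counted each. From 21 to 22 Mb, nearer CDK8, none of 6 did, and 6 genes there are at least 4-fold lower in jazDcdk8-1 than in Col-0. Changes of genes in the interval, among them MYC5, DFR, TSB1, ASB2, MYB111, UGT79B1, CYP81F2, PDF1.2A and PDF1.2C, cannot be told apart from such segments in jazD.

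The negative interactions named by the rule were AT5G47260 (-10.5), PDF1.3 (-8.34), PDF1.2C (-7.98), PDF1.2B (-7.14) and ACT (-6.52). All 5 depend on cdk8-1 replicate 3: without that library edgeR calls none of them. PDF1.3 and PDF1.2C then stand at -3.22 and -4.72, while AT5G47260, PDF1.2B and ACT have 2 counts or fewer left in cdk8-1, which gives no size. AT5G47260 has 0 counts in Col-0, 2 in cdk8-1, 297 in jazD and 1 in jazDcdk8-1, so its -10.5 is a fitted value over groups near 0 and gives no size. PDF1.3 has 1, 3 and 222 counts and ACT 0, 0 and 44 in cdk8-1 replicates 1, 2 and 3. In 15 genes high in jazD, the excess in replicate 3 over the other 2 cdk8-1 libraries is 0.262 to 0.88% of the jazD level (median 0.491%). Material from jazDcdk8-1 is argued against, since its share would range 29.28-fold between genes (1.944 to 56.91%). More than 1 cause stays open. A trace of jazD reads or RNA may be present, with shares that range 3.354-fold, between the bounds of 2 and 5 set for the test; its baseline was changed to the other 2 cdk8-1 libraries after a first run with all libraries of intact JAZ genes, the bounds were not. A pool with some plants in an induced jasmonate response may also be the source: AT5G28810 and AT5G47260, otherwise at 0 with intact JAZ genes, have 5 counts together there, too few to decide. AT5G47260 also lies in the chromosome 5 interval, so its level in jazD may follow the segment and not a jasmonate response, and its counts say less about such a pool. The 2 cannot be told apart here, and either way the low defensin and ACT level of cdk8-1 rests on 2 libraries.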

How the results depend on the processing

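Total-count scaling and the removal of chromosome 5 from 17 to 24 Mb from the finished results were chosen after the data were seen. RLE scaling, the CPM filter and removal of the 20 most abundant genes lost none of the named-gene calls they could test (687, 670 and 677). Of 687 named calls DESeq2 lost 36 and gave no adjusted p for 13, limma on log2(TPM + 1) lost 45 of 677, and leaving out 1 library lost 16 to 38. Of simulated 1.5-fold changes, drawn without genes of low counts, 59.7% were recovered in the interaction and 77.6% in jazDcdk8-1 against jazD. Neither depth nor the number of libraries was varied.

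With limma on log2(TPM + 1), cdk8-1 against Col-0 gave 3894 genes higher and 1673 lower, jazDcdk8-1 against jazD 6380 and 2006, and jazDcdk8-1 against Col-0 2001 lower; 1315 genes were higher in jazD and lower again and 3334 the reverse, with a Spearman coefficient of 0.456 between the 2 cdk8-1 effects. With log2(TPM + 0.1) these were 3856, 1681, 6401, 1965, 1977, 1243 and 3407, with 1023 negative interactions. Both change test, pseudocount and scaling together. Total counts in place of TMM, which change the scaling alone, gave 3922 genes higher in cdk8-1. NINJA in jazDcdk8-1 against jazD, at -0.13 with DESeq2, turned to 0.01 under both limma settings. The median of all genes in that comparison was 0.132 log2 with log2(TPM + 1) and 0 under TMM. The turn of NINJA is thus about the size of this shift of all genes. Requiring a change of at least 2-fold leaves fewer genes by construction: 189 and 471, 817 and 435, 298 and 850, 369 and 521, and 161 and 292 interactions, with overlaps of 490 and 136 and a Spearman coefficient of 0.561. Without a filter the coefficients were 0.272 (Pearson) and 0.339 (Spearman), with more genes of few counts included; without the chromosome 5 interval they were 0.577 and 0.457.

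With an estimated correlation camera called 2, 10, 9, 8 and 7 lists (cdk8-1, jazD, jazDcdk8-1 against jazD, jazDcdk8-1 against Col-0, interaction), 54 of 200 list calls lost and none gained, and fry called 29, 33, 35, 24 and 20; it gained 54 and lost 3, all in the interaction: MYC-branch defense (adjusted p = 0.0876), camalexin (adjusted p = 0.0881) and photosynthesis (adjusted p = 0.113). Leaving out 1 library moved the Pearson coefficient between 0.483 and 0.541 and the Spearman coefficient between 0.418 and 0.454, and ACT in the interaction down to -7.22; the 0.32 without cdk8-1 replicate 3 rests on no ACT counts in cdk8-1 and is no bound. Same-numbered libraries of different genotypes did not correlate (0 of 18 pairs above 0.1), so replicates were not paired, and a block for replicate number lost 7 of 687 named calls and 1 list call and gained 1.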

Other observations

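Of the tests in this part, that of a jaz effect on clock genes was chosen after the result was seen.

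Single iron, auxin and abscisic acid genes fell where CDK8 was lost, while most of their lists were not called. Of 11 iron genes 5 fell and 2 rose in cdk8-1 against Col-0 (camera adjusted p = 0.332; 4 and 4 with total counts), and 6 fell and 1 rose in jazDcdk8-1 against jazD (adjusted p = 0.0392, and adjusted p = 0.141 with an estimated correlation). Of 11 auxin genes 5 fell and 1 rose in each (adjusted p = 0.0559 and 0.0640). Of 6 abscisic acid genes 5 fell and 1 rose in cdk8-1 (adjusted p = 0.00701, and adjusted p = 0.159 with an estimated correlation), and 2 fell and 1 rose in jazDcdk8-1 against jazD (adjusted p = 0.451; 1 and 1 with total counts). In cdk8-1 against Col-0 the iron-regulated factors BHLH100 (-2.96 ± 0.59) and BHLH38 (-2.57 ± 0.49) and the iron store gene FER1 (-1.47 ± 0.10) fell, and in jazDcdk8-1 against jazD so did BHLH38 (-3.13 ± 0.71), FER1 (-1.78 ± 0.10) and BHLH100 (-1.64 ± 0.54), log2 fold changes with n = 3 per group. The auxin-induced genes IAA19 (-0.86 ± 0.14 and -0.80 ± 0.15) and IAA29 (-0.85 ± 0.18 and -0.72 ± 0.20) fell in both comparisons, and GH3.3, which conjugates auxin, fell in both (-0.92 ± 0.19 and -1.77 ± 0.16) and rose in jazD (1.4 ± 0.15). The dehydrin gene RAB18, induced by abscisic acid, fell by 1.02 ± 0.14 and 1.37 ± 0.14. The mitochondrial stress genes OM66 (-1.30 ± 0.20 and -1.25 ± 0.18) and AOX1D (-2.66 ± 0.86 and -2.89 ± 0.64) fell as well, but NDB2 (0.31 ± 0.11) and NAC013 (0.36 ± 0.10) rose in cdk8-1. The NDB2 call is lost with DESeq2 and without Col-0 replicate 1 or 2 or cdk8-1 replicate 3, and that of NAC013 without Col-0 replicate 3 or cdk8-1 replicate 1. Of 9 genes of that list 4 fell and 2 rose in each comparison (adjusted p = 0.709 and 0.509). With total counts 3 fell and 5 rose in cdk8-1 and 3 and 3 in jazDcdk8-1 against jazD, so the direction turns with the scaling.

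Nitrate and cold genes went both ways, and cell cycle genes fell in part in jazD. Of 12 nitrate genes 7 fell and 3 rose in jazD (adjusted p = 0.00944), 5 rose and 3 fell in cdk8-1 (adjusted p = 0.00394) and 6 rose and 4 fell in jazDcdk8-1 against jazD (adjusted p = 0.0356). With an estimated correlation these became 0.2135, 0.2332 and 0.299. The nitrate reductase gene NIA1 fell in jazD (-1.06 ± 0.07), rose in cdk8-1 (0.83 ± 0.07) and rose in jazDcdk8-1 against jazD (1.00 ± 0.07), as did NIR1 (-0.49 ± 0.04, 0.70 ± 0.04 and 0.75 ± 0.04), while NIA2 fell in all 3 comparisons (-0.40 ± 0.05, -0.29 ± 0.05 and -0.30 ± 0.05). The cold-induced genes COR47 (0.92 ± 0.05 and 0.68 ± 0.05) and COR15A (0.75 ± 0.09 and 0.81 ± 0.10) rose where CDK8 was lost in either background, while GOLS3 fell in both (-0.81 ± 0.12 and -1.61 ± 0.18) and CBF3 fell in cdk8-1 (-0.55 ± 0.15) and rose in jazDcdk8-1 against jazD (0.58 ± 0.16). Of 10 cold genes 3 rose and 3 fell in cdk8-1 (adjusted p = 0.0404, and adjusted p = 0.471 with an estimated correlation), and 5 rose and 1 fell in jazDcdk8-1 against jazD (adjusted p = 0.156). Of 24 cell cycle genes 12 fell in jazD (adjusted p = 0.0554), CYCB1;1 by 0.59 ± 0.16 and CDKB2;2 by 0.58 ± 0.10, and in jazDcdk8-1 against jazD 2 fell and 12 rose (adjusted p = 0.0640), with CDKB2;2 at 0.71 ± 0.10 and AUR1 at 0.68 ± 0.12. The tocopherol genes VTE1 (-0.63 ± 0.06 in jazD, 0.60 ± 0.06 back) and VTE4 (-0.35 ± 0.10, 0.74 ± 0.10) moved likewise. Of the 8 genes of their list 5 fell and 2 rose in jazD (adjusted p = 0.214), and 3 rose and 2 fell in jazDcdk8-1 against jazD (adjusted p = 0.101).

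Clock genes moved in jazD. In 11 further clock-controlled genes, the 6 with a dawn peak had a median of -1.09 log2 in jazD against Col-0 and the 5 with an evening peak one of 1.47, a difference of 2.56; COL2 fell by 1.99 and FKF1 rose by 2.28. An earlier harvest of jazD was set to give a negative difference, and the 2.56 is positive. That prediction holds only for some hours of the day. Since the hour is not stated, the test cannot exclude an earlier harvest. A later harvest of jazD may give the 2.56, and so may an effect of the jaz mutations on these genes (evening median 1.47). The hour of harvest is not stated for any genotype, and both would move these genes alike, so the second cannot be told apart from the first. In jazDcdk8-1 against Col-0 the difference was 1.54 (dawn -0.71, evening 0.84), in jazDcdk8-1 against jazD -0.88 and in cdk8-1 against Col-0 -0.40. GRP7 and other genes with a daily rhythm carry this difference in the comparisons of the report.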
